A study of Homo sapiens with 4 samples.

How the data were processed

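RNA of BJ cells was measured on 4 two-colour Agilent gene expression arrays of 1 slide. BJ cells are fibroblasts from human foreskin kept as an established strain. Per the labels' protocols, cells at about 45 population doublings were grown in 15% serum and 3% oxygen, infected with retroviral vectors carrying an shRNA against BRD7 or the control shRNA FF2, and selected for 5 days with 1 ug/ml puromycin. Total RNA (1.5 ug) was labelled with Cy3 for BRD7 shRNA cells and with Cy5 for control cells on every array, per the labels. The groups were untreated and nutlin-3a-treated (8 uM), with 2 arrays each and 1 array per hairpin in each. The hairpin number served as the replicate number. The labels do not say whether the arrays came from separate cultures, or whether arrays shared a control extract, so p-values measure only the spread between these arrays, which may be partly technical. The control is the second channel of each ratio, and a test of the ratio against 0 leaves out the control's own spread. All arrays lay on 1 slide, so no batch of slides could be tested.

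The authors deposited scanner output and a table of processed values. The intensity values used here are the median pixel brightness of each spot and of its local background per dye, not normalized, per the file headers and column names. The processed intensity columns hold background-subtracted, dye-normalized signals of Agilent Feature Extraction, whose version is 8.5.1.1 per the submitters' processing notes and 10.5.1.1 per the file headers. The header text is identical in all 4 files and describes a grid of 384 by 164 where the spots form 532 by 85, so its settings were not relied on. The deposited log10 ratios of red over green in the table of the whole series were equal to the log10 ratios of the scanner output for every spot (largest difference 0, median 0 on each array), which settles their scale and direction; between 12.8% and 20.3% of spots per array are listed at 0. They give control over BRD7 shRNA, and their sign was turned here. The flags for spots well above background, saturated or irregular are 0 or 1 values deposited by the authors.

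The design fixed before the data were examined took the mean spot signal and the median background. The mean was not among the columns used here, so median signals replaced it. Background was corrected with normexp (offset 50), and the log ratio was normalized within each array by loess with control spots given no weight. Of 44793 spots 1417 were controls, and spots with outlier flags were left out (239, 271, 426 and 217 per array), which removed 348 probes. Spots of the same probe were averaged to 41000 probes. A probe entered the tests when it was well above background in at least 1 channel on at least 2 of the 4 arrays, which 29806 probes met. Accessions were matched to a RefSeq gene table for current symbols, and 24794 probes (60.5%) had a symbol. A gene was represented by its probe with the highest mean intensity, which gave 13646 named genes and 9643 unnamed probes, 23289 in all. No coordinates are given because no genome build is named in the sources used here. A level not well above background on any array of a group was treated as a bound: each array's value was the higher of its own signal and the lowest signal well above background, and the fold is then given as at least that size.

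A further step departs from that design. Copies of the same probe sequence spotted 10 times differed along the rows of the array, with correlations between log ratio and row of 0.846, 0.848, 0.702 and 0.206 over 169 bright probes. A trend over the array surface was therefore fitted on each array by a 2-dimensional loess (span 0.1). It was fitted for the log ratio and also for the mean log2 intensity, taken as a deviation from the mean over the arrays. Both trends were removed from the signals of the dyes before the averaging, so the step also acts on the responses read in separate channels. This was chosen after the files were seen; 3 spans were tried (0.05, 0.1 and 0.3) and the numbers of genes they called were seen, and 0.1 was kept. The reported values have this step, and the values of the design as fixed are given beside each comparison and in the closing section. The standard deviation of the copies was 0.0782, 0.0838, 0.128 and 0.0939 after it and 0.0977, 0.102, 0.168 and 0.107 in the processed signals of Feature Extraction.

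Comparisons of BRD7 shRNA with control cells used limma (lmFit and eBayes) on the log2 ratios of all 4 arrays with 1 mean per condition, which left 2 residual degrees of freedom and a prior of 3.97. The difference between conditions is the difference of these means, and the hairpins were compared in a fit with condition and hairpin (1 residual degree of freedom). The nutlin-3a response of each cell type came from limma's fit of separate channels after Aquantile normalization between arrays, with an intraspot correlation of 0.487. Adjusted p-values are Benjamini-Hochberg values over all 23289 tests, with a threshold of 0.05. Errors are the model's standard errors. Gene lists were written before the data were examined and were tested with limma's camera (preset correlation 0.01, adjusted over 21 lists), again with an estimated correlation, and with fry. With an estimated correlation camera has only the residual degrees of freedom of the fit (2, or 1 for the hairpins). The p53 list in control cells lost its call that way (adjusted p = 0.101), although its estimated correlation of 0.00928 lay below the preset. For a list of low correlation, a lost call is therefore not shown to come from correlation between genes. The G2/M and G1/S lists differed, with estimated correlations of 0.569 and 0.580 in the untreated comparison. Their lost calls there may come from correlation, and the preset of 0.01 may make their adjusted p too small. The lists cover p53 activated targets, G2/M, G1/S and DNA replication, SWI/SNF subunits, secretory factors of senescent cells, interferon-stimulated genes, extracellular matrix, contractile genes with SRF or YAP targets, immediate early genes, hypoxia, the unfolded protein and amino acid stress response, heat shock, ribosomal proteins, oxidative phosphorylation, cholesterol synthesis, NRF2 targets, the TGF-beta response, and markers of keratinocytes, melanocytes, endothelial cells and leukocytes.

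Genes named in the text follow a rule fixed before the data were examined. It takes a fixed set of genes always, among them BRD7, MDM2, MDM4, CDKN1A, PBRM1, CDKN2A, GDF15, TP53INP1, BTG2, TP53I3, CCNG1, SESN1, PLK3 and FAS. Per comparison it adds the 10 largest rises and 10 largest falls among genes past the threshold with the same sign on every array, without unnamed probes; where fewer than 5 pass in a direction it takes the 5 of smallest p, said not to pass. From each list past the threshold it adds up to 4 members of smallest p in the direction of the shift. The text prints a selection of these, and a few genes the rule takes are not reported here.

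Each fit was tested on simulated data in which 100 genes were changed 2-fold and 100 were changed 4-fold. Of the genes changed 2-fold it recovered 96% for the untreated comparison, 97% for the nutlin-3a comparison, 87% for the difference between conditions, 98% over all arrays, 79% for the hairpins, 89% for the response of control cells and 90% for that of BRD7 shRNA cells. Neither changes under 2-fold nor a dye bias were simulated. In the data only 90 of 3057 calls untreated and 148 of 5156 with nutlin-3a reached 2-fold. The recovery of most called sizes was therefore not tested. In a simulation of the list test over all arrays, a set of 40 genes shifted by 0.5 was called and 0 of 20 unshifted sets were. The simulated genes were independent, whereas the estimated correlation over all arrays was 0.569 for the G2/M list and 0.580 for the G1/S list. False calls of lists with correlated genes were therefore not tested.

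Alternatives set before the data were examined were the Feature Extraction processed signals, no background correction, an offset of 10, median centring in place of loess, the authors' deposited ratios, no filter and a strict filter on dim probes, the mean over a gene's probes, an intensity trend with robust variances, the hairpin number as a block, single channels, other normalizations between arrays, only the arrays of a comparison, and leaving out each array in turn. In the fits of separate channels with 3 arrays the intraspot correlation of all arrays was kept. Software was R 4.3.3 with limma 3.58.1, data.table (version 1.17.8) and jsonlite 2.0.0.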

Results

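RNA levels were compared between BRD7 shRNA and control shRNA in BJ cells, human foreskin fibroblasts kept as an established cell strain. BRD7 is a bromodomain protein and a subunit of the PBAF chromatin remodelling complex, and has been described as a cofactor of p53. Cells were left untreated or were given nutlin-3a, a small molecule that blocks the binding of MDM2 to p53 and so stabilises p53. Each of 4 two-colour arrays carried RNA of BRD7 shRNA cells in Cy3 and RNA of control shRNA cells in Cy5. There were 2 untreated arrays and 2 nutlin-3a arrays, and in each condition 1 array held hairpin 1 and 1 array held hairpin 2. The sample titles give 6 hours of nutlin-3a for hairpin 1 and 8 hours for hairpin 2, while the treatment protocol gives 8 uM for 8 hours. The number of arrays limits the precision of every value. The dyes were not swapped on any array, so a dye bias of a single gene is part of each comparison of BRD7 shRNA with control cells. A constant dye bias cancels in the response of one cell type to nutlin-3a and in the difference between 2 responses. All signed values give BRD7 shRNA over control or nutlin-3a over untreated, so the ratios run opposite to those the authors deposited.

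The median spot signal was 159, 172, 149 and 165 in Cy3 and 71.5, 71, 62 and 57 in Cy5, for untreated hairpins 1 and 2 and then nutlin-3a hairpins 1 and 2. The local background was between 16.5 and 18 in Cy3 and was 35 in Cy5, and the share of probes well above background was between 68.3% and 79.0% in Cy3 and between 54.9% and 64.3% in Cy5. The number of saturated spots was 0 on each array. Across genes, the log ratios of pairs of arrays had Pearson correlations between 0.636 and 0.782; genes are not independent replicates. The log ratio followed the row of the spot on all 4 arrays. On the nutlin-3a array of hairpin 2 it did so as an arc, with a median of -0.25 in the lowest, up to 0.29 in the middle and -0.25 in the highest rows for bright probes. Copies of 1 sequence spotted 10 times had a standard deviation of 0.33, 0.38, 0.41 and 0.24 log2 units over the array surface, and of 0.08, 0.08, 0.13 and 0.09 after a smooth trend over the surface was removed. The values reported here have this trend removed. That step was added after the files were seen and departs from the design fixed beforehand, so the counts of the fit without it stand beside each comparison.

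**Figure D1:**
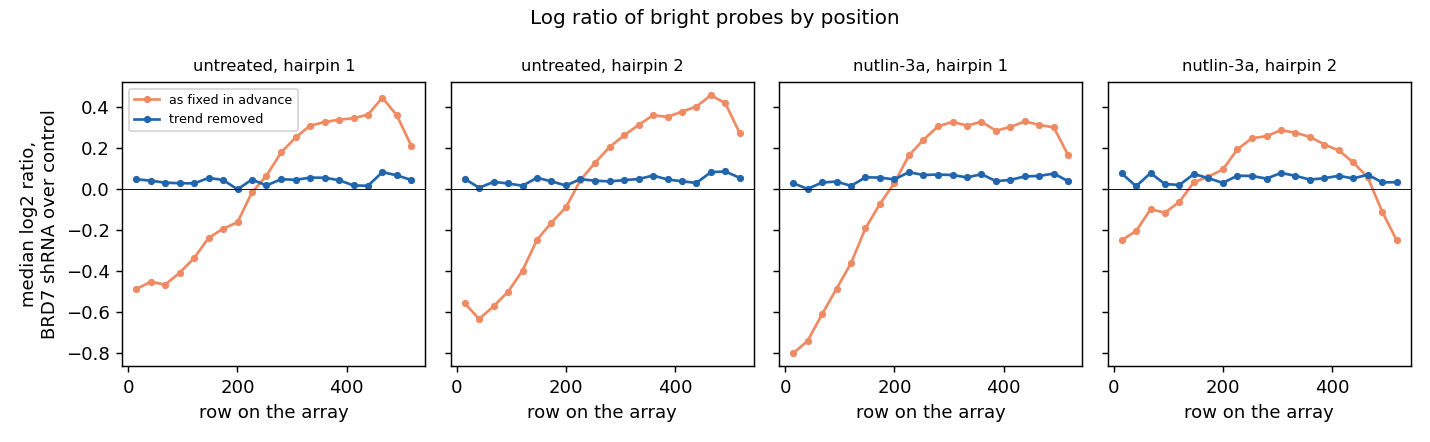
Median log2 ratio of BRD7 shRNA over control of bright probes (mean log2 intensity over 8) against the row on the array, 1 panel per array. Orange points are the values of the design fixed in advance, whose lowest point was at -0.49, -0.63, -0.80 and -0.25 in panel order; blue points are the values with the trend removed.

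The BRD7 transcript was 30.7-fold lower in BRD7 shRNA cells than in control cells, at 3.26% of the control level. Its single probe (A_32_P18824) was well above background in both channels on all 4 arrays. The log2 ratio was -4.80 and -5.09 on the untreated arrays with hairpins 1 and 2 and -4.71 and -5.16 on the nutlin-3a arrays, with a mean of -4.94 ± 0.22 (SD, n = 4). With the Feature Extraction signals BRD7 was 56.8-fold lower, at 1.76% of the control level. Nutlin-3a left BRD7 at a log2 response of 0.08 in control cells (SE 0.17, limma adjusted p = 0.838), and at -0.39 in the design as fixed (SE 0.20, adjusted p = 0.408). PBRM1, the gene of another PBAF subunit, was 1.12-fold higher in BRD7 shRNA cells over all arrays (log2 0.16, SE 0.05, adjusted p = 0.0452). Its 3 probes differed in size, as the 2 not used had log2 ratios of 0.34 and 0.64 in untreated and 0.37 and 0.58 in treated cells.

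In untreated cells the knockdown was tested first, as the design compares the 2 shRNAs in each condition. Cell cycle genes were higher in BRD7 shRNA cells. Of 43 measured genes of the G2/M list 30 were higher, 1 was lower and 12 did not pass, with a median log2 ratio of 0.43 (camera adjusted p = 1.34e-13, or adjusted p = 0.750 with an estimated correlation). ECT2, a regulator of cytokinesis, was 1.61-fold higher (log2 0.69, SE 0.07, n = 2), the chromosomal passenger gene CDCA8 1.72-fold (SE 0.08) and the spindle gene HMMR 1.51-fold (SE 0.06). In the G1/S and DNA replication list 14 of 46 genes were higher, 1 was lower and 31 did not pass (median 0.31, camera adjusted p = 1.77e-07, or adjusted p = 0.750 with an estimated correlation). CHAF1B, a subunit of the histone chaperone CAF-1, was 1.56-fold higher (log2 0.64, SE 0.10), and POLA1, the catalytic subunit gene of DNA polymerase alpha, 1.43-fold (SE 0.08). Adjusted over the list alone, 36 G2/M genes were higher and 1 lower, and 28 and 1 in the other list. Without untreated replicate 2 the median of the G1/S list was 0.19.

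Among named genes other than BRD7, the largest differences in untreated cells lay outside these lists. CXCL1, a chemokine that attracts neutrophils, was 5.46-fold higher (log2 2.45, SE 0.15, n = 2, adjusted p = 0.00356). ARL6IP1, a membrane-shaping protein of the endoplasmic reticulum, was 4.21-fold higher (SE 0.09), LYPD1 3.44-fold (SE 0.07), the copper transporter gene SLC31A2 3.20-fold (SE 0.06) and ADA, adenosine deaminase, 3.16-fold (SE 0.09). SBSPON, a secreted matrix protein, was 5.11-fold lower (log2 -2.35, SE 0.14), ACKR4, a scavenging chemokine receptor, 4.44-fold lower (SE 0.10), and SLC38A11, an amino acid transporter gene, 3.48-fold lower (SE 0.07). CDKN2A, which encodes p16INK4A and ARF, was 1.53-fold higher (log2 0.61, SE 0.06, adjusted p = 0.00846), and the death receptor gene FAS 1.30-fold (SE 0.07, adjusted p = 0.0224). CDKN1A, the gene of the p53-induced inhibitor p21, had a log2 ratio of -0.28 (SE 0.07) and did not pass (adjusted p = 0.0580). Its second probe, not used in this test, had a mean log2 ratio of -0.41 in untreated and -0.81 in treated cells. The missing call may therefore depend on the probe chosen. Of 37 hypoxia response genes 5 were lower and none higher, adjusted over the list alone too (median -0.09, camera adjusted p = 0.00533), but with median centring in place of loess the list was called upwards, 0.22 above the median of all genes. Of 54 cytosolic ribosomal protein genes 12 were lower and none higher, 16 adjusted over the list alone (median -0.14, adjusted p = 4.75e-06), but this list too was called upwards with median centring, 0.02 above all genes. Both had an adjusted p of 0.750 with an estimated correlation and did not pass with the Feature Extraction signals (adjusted p = 0.0584 and 0.879), nor did the hypoxia list without untreated replicate 2 (0.148). The median of the hypoxia list was -0.21 without untreated replicate 1 and -0.03 without untreated replicate 2. The 67 p53 activated targets did not pass as a list (median 0.01, camera adjusted p = 0.822), with 8 members higher and 6 lower, or 22 and 13 adjusted over the list alone.

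Of 23289 genes and unnamed probes tested in untreated cells, 3057 passed (1926 higher, 1131 lower), 90 of them by at least 2-fold. The design as fixed gave 6405, the Feature Extraction signals 0 (6735 at an unadjusted p under 0.05, smallest adjusted p 0.0816), no background correction 4, an offset of 10 gave 12, and median centring, under which the median of all tested genes was 0.55, gave 20396. The count also depended on single arrays, at 383 without untreated replicate 1, 28 without untreated replicate 2 and 5527 without either one of the nutlin-3a arrays.

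In nutlin-3a-treated cells nearly the whole G2/M list was higher with the knockdown. Of its 43 genes 40 were higher and none lower (median log2 ratio 0.82, camera adjusted p = 1.26e-22, or adjusted p = 0.446 with an estimated correlation). Among them were CDCA8 at 2.79-fold (log2 1.48, SE 0.08, n = 2), ECT2 at 2.27-fold (SE 0.07), the spindle gene DLGAP5 at 2.18-fold (SE 0.07) and HMMR at 1.99-fold (SE 0.06). Of 46 G1/S and replication genes 38 were higher and none lower (median 0.63, camera adjusted p = 4.70e-16, or adjusted p = 0.446 with an estimated correlation). These included GINS3, part of the replicative helicase, at 2.32-fold (SE 0.11), CHAF1B at 2.15-fold (SE 0.10) and UHRF1, which reads hemimethylated DNA at replication forks, at 2.04-fold (SE 0.10). E2F2, a transcription factor of the G1/S transition, was 2.91-fold higher (SE 0.12). Adjusted over the list alone, 41 G2/M genes were higher, and 43 of the other list were higher and 1 lower.

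Of 67 p53 activated targets 21 were lower in BRD7 shRNA cells under nutlin-3a, 6 were higher and 40 did not pass; adjusted over the list alone 21 were lower and 7 higher. The camera test of the list gave a median of -0.10 and an adjusted p of 0.00177, but with median centring the list was called upwards, 0.26 above the median of all genes, which was 0.68. The adjusted p was 0.446 with an estimated correlation and 0.142 in the design as fixed. Without nutlin-3a replicate 2 the median was -0.05 (adjusted p = 0.0312). TNFRSF10C, a decoy receptor for the death ligand TRAIL, was 2.13-fold lower (log2 -1.09, SE 0.10), CDIP1, a proapoptotic gene, 1.70-fold lower (SE 0.08), and CDKN1A 1.60-fold lower (log2 -0.67, SE 0.07, adjusted p = 0.00540). GDF15, a stress-induced cytokine gene, was 1.68-fold lower (SE 0.15, adjusted p = 0.0207). PLXNB2, another of the 4 members of smallest p, was 1.44-fold lower (log2 -0.53, SE 0.06), a direction that turned with median centring. MDM2 had a log2 ratio of -0.03 (SE 0.06), BTG2 -0.27 (SE 0.10) and SESN1 -0.13 (SE 0.09), and none of these passed.

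ARL6IP1 was 5.81-fold higher in treated BRD7 shRNA cells (log2 2.54, SE 0.09), CXCL1 3.69-fold (SE 0.15), FAM107B 3.46-fold (SE 0.10) and SHCBP1, a gene used in cytokinesis, 3.19-fold (SE 0.07). SBSPON was 6.26-fold lower (log2 -2.65, SE 0.14) and GAL, the gene of the neuropeptide galanin, 2.82-fold lower (SE 0.08). Of the hypoxia list 10 genes were lower and 2 higher, 12 and 2 adjusted over the list alone (median -0.13, camera adjusted p = 0.000517), but with median centring the list was called upwards, 0.32 above all genes. Its median was -0.20 and -0.08 without nutlin-3a replicates 1 and 2. Of the ribosomal list 17 were lower and 1 higher, 23 and 1 adjusted over the list alone (median -0.20, adjusted p = 5.18e-09), and it too was called upwards with median centring, 0.02 above all genes. Their adjusted p was 0.446 with an estimated correlation, and the ribosomal list did not pass with the Feature Extraction signals (adjusted p = 0.572). In all 5156 genes and probes passed (3165 higher, 1991 lower), 148 by at least 2-fold, against 4666 in the design as fixed and 1887 with the Feature Extraction signals. Without background correction none passed (7468 at an unadjusted p under 0.05), with an offset of 10 there were 2717 and with median centring 20876, while leaving out any 1 array gave between 3522 and 4162.

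The knockdown effect was then taken over both conditions. ARL6IP1 was 4.95-fold higher (log2 2.31, SE 0.07, n = 4, adjusted p = 0.000110), CXCL1 4.49-fold (SE 0.11), LYPD1 3.28-fold (SE 0.05) and NPPB, the gene of brain natriuretic peptide, 2.63-fold (SE 0.12). SBSPON was 5.66-fold lower (log2 -2.50, SE 0.10), ACKR4 3.28-fold lower (SE 0.07), TNFRSF11B, which encodes osteoprotegerin, 3.03-fold lower (SE 0.11), and the cation channel gene TRPV2 3.01-fold lower (SE 0.09). The trypsinogen genes PRSS2 and PRSS3 were 2.97-fold and 2.92-fold lower, but they are near-identical copies whose probes may not tell them apart. CDKN2A was 1.44-fold higher (SE 0.05, adjusted p = 0.00129), CDKN1A 1.39-fold lower (log2 -0.48, SE 0.05, adjusted p = 0.00223) and GDF15 1.55-fold lower (SE 0.10, adjusted p = 0.00710). The size for GDF15 differed between hairpins. Its log2 ratios, untreated and then treated, were -0.27 and -0.53 with hairpin 1 and -0.76 and -0.96 with hairpin 2. FAS was 1.20-fold higher (SE 0.05, adjusted p = 0.00998), and CCNG1, a p53-induced cyclin gene, was 1.12-fold lower (log2 -0.16, SE 0.04, adjusted p = 0.0289), but higher in the design as fixed (log2 0.21, adjusted p = 0.0359) and with median centring. The ratios of MDM2 (log2 0.09), MDM4 (0.07), TP53INP1 (0.07), BTG2 (-0.11), TP53I3 (0.00), SESN1 (0.07) and PLK3 (-0.25) did not pass. With median centring, relative to the median of all genes, MDM2 was lower (-0.47, adjusted p = 0.000369, with a control signal well above background on only 2 of 4 arrays) and BTG2 higher (0.36, adjusted p = 0.00625), and MDM4 was lower in the design as fixed (-0.36, adjusted p = 0.0402).

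Of the G2/M list 41 of 43 genes were higher over all arrays and none lower, adjusted over the list alone too (median 0.62, camera adjusted p = 1.82e-17, or adjusted p = 0.532 with an estimated correlation). Of the G1/S and replication list 40 of 46 were higher and 1 lower, 43 and 1 adjusted over the list alone (median 0.48, adjusted p = 2.63e-12, or 0.532 as an adjusted p with an estimated correlation). The median of the G2/M genes was 0.35, 0.50, 0.75 and 0.87 on the single arrays, and that of the G1/S genes 0.19, 0.41, 0.54 and 0.74, so both lay above 0 on 4 of 4 arrays. The p53 list did not pass (median -0.03, camera adjusted p = 0.102), with 16 members higher, 25 lower and 26 not passed, or 19 and 26 adjusted over the list alone. The hypoxia list had 2 genes higher and 15 lower (2 and 16 adjusted over the list alone, median -0.13, adjusted p = 0.000612), but was called upwards with median centring, 0.23 above the median of all genes, which was 0.62. Its median depended on single arrays, at -0.19 and -0.06 without untreated replicates 1 and 2 and -0.07 without nutlin-3a replicate 2, and was -0.03, -0.21, -0.08 and -0.20 on the single arrays. The ribosomal list had 2 genes higher and 24 lower (2 and 29 adjusted over the list alone, median -0.17, adjusted p = 2.95e-08), but was called upwards with median centring, although its median then lay -0.01 from that of all genes. The adjusted p of both lists was 0.532 with an estimated correlation, and the ribosomal list did not pass with the Feature Extraction signals (adjusted p = 0.636). With fry the G2/M and ribosomal lists passed (adjusted p = 0.0415 and 0.0370), and the G1/S and hypoxia lists did not (0.0814 and 0.150). STC2, a secreted glycoprotein gene of the hypoxia list, was 1.63-fold lower (SE 0.09), and RPL18 1.57-fold lower (SE 0.05). In all, 8343 genes and probes passed (5157 higher, 3186 lower), 39 by at least 2-fold upwards and 47 downwards, against 9642 in the design as fixed, of which 4795 were shared, and 6248 with the Feature Extraction signals. Without background correction 5080 passed and with median centring 21502, and 4661 without untreated replicate 1 or 3902 without untreated replicate 2. Between the untreated and the treated comparison 1560 calls were shared upwards and 938 downwards and 1 was opposite, where independent lists would share 262 and 96.7. Both comparisons had the same dye orientation and their arrays may share a control extract, so part of the excess may come from dye bias or a shared control.

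**Figure D2:**
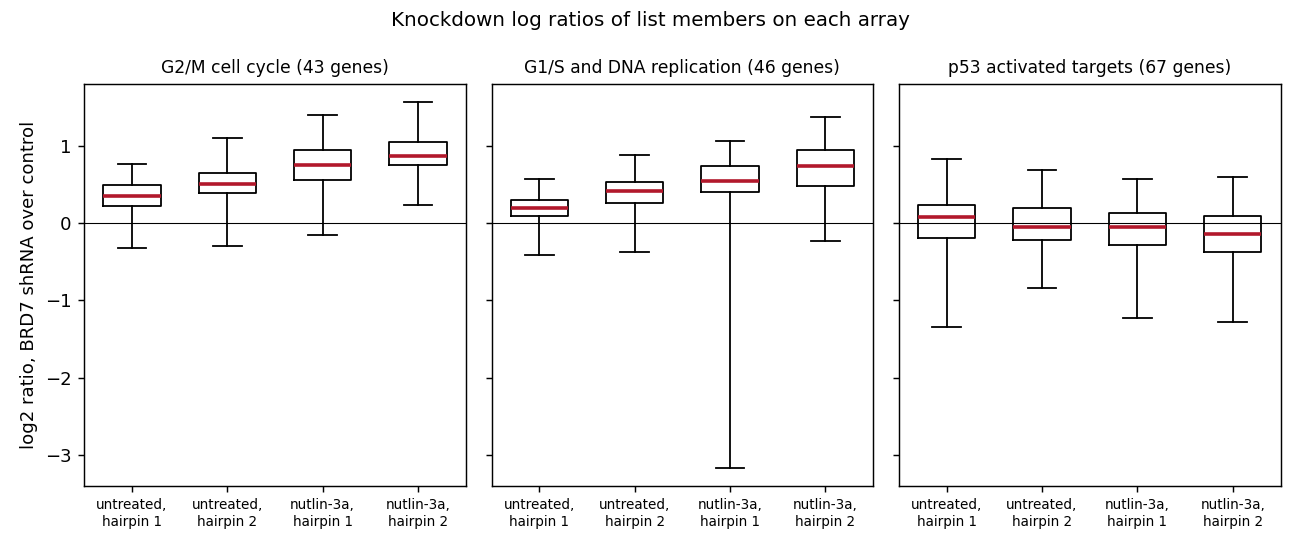
Log2 ratio of BRD7 shRNA over control on each array for the measured members of 3 gene lists; the red line is the median, the box the quartiles and the whiskers the full range over genes. The medians of the G2/M list are 0.35, 0.50, 0.75 and 0.87 from left to right, those of the G1/S and replication list 0.19, 0.41, 0.54 and 0.74, and those of the p53 list 0.07, -0.06, -0.05 and -0.15.

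Nutlin-3a raised p53 target genes in control cells. BTG2, an antiproliferative gene, rose 6.21-fold (log2 2.63, SE 0.13, n = 2 per state, adjusted p = 0.000343), CDKN1A 4.36-fold (log2 2.12, SE 0.11), TP53INP1 4.12-fold (SE 0.09), GDF15 3.90-fold (SE 0.22) and SESN1, a stress-induced inhibitor of mTORC1, 3.80-fold (SE 0.12). MDM2, which encodes the ubiquitin ligase whose binding to p53 is blocked by nutlin-3a, rose at least 2.99-fold (log2 1.58, adjusted p = 0.000343). This is a bound, as the MDM2 signal in untreated control cells was not well above background on either array. FAS rose 1.62-fold (SE 0.08), TP53I3 1.55-fold (SE 0.10) and CCNG1 1.53-fold (SE 0.07). Of the 67 p53 targets 27 rose, none fell and 40 did not pass (median 0.44, camera adjusted p = 9.22e-23, or adjusted p = 0.101 with an estimated correlation), and 45 rose and 1 fell adjusted over the list alone. The list passed with fry (adjusted p = 0.00678). MDM4 (log2 0.02), CDKN2A (0.30) and PLK3 (0.93) did not pass.

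Cell cycle genes fell in control cells under nutlin-3a. Of the G2/M list 16 of 43 genes fell and none rose (median -0.45, camera adjusted p = 2.28e-22, or adjusted p = 0.213 with an estimated correlation), and 32 fell adjusted over the list alone. CDCA8 was 2.10-fold lower (log2 -1.07, SE 0.11) and the mitotic kinase gene PLK1 1.93-fold lower (log2 -0.95, SE 0.10). Of the G1/S and replication list 12 of 46 fell and none rose (median -0.44, camera adjusted p = 1.21e-21, or adjusted p = 0.101 with an estimated correlation), and 28 fell and 1 rose adjusted over the list alone. The replication licensing gene CDT1 was 3.00-fold lower (log2 -1.59, SE 0.17), UHRF1 2.36-fold lower (SE 0.16) and CCNE1, the gene of cyclin E1, 2.11-fold lower (SE 0.13). E2F2 was 3.71-fold lower (log2 -1.89, SE 0.17). Among named genes the largest falls outside the lists were those of the hair keratin-associated gene KRTAP1-5 (3.75-fold, SE 0.16) and the membrane protein gene TM4SF1 (3.72-fold, SE 0.14). Lists of secretory factors (median -0.16, adjusted p = 0.000583, 2 of 34 fell), matrix genes (-0.12, 0.000329, 1 of 40), contractile genes (-0.16, 0.00565, 2 of 22) and immediate early genes (-0.13, 0.00968, 5 of 27 fell and 1 rose) passed downwards. The list of NRF2 targets passed upwards (0.13, 0.00671, 1 of 19 rose). In that order, the adjusted p of these 5 lists with an estimated correlation was 0.252, 0.426, 0.353, 0.289 and 0.289. With fry the G1/S list passed (adjusted p = 0.00678), as did the G2/M, secretory, immediate early and NRF2 lists (0.0177 each). The matrix and contractile lists did not pass with fry (adjusted p = 0.124 and 0.0930). TNFAIP3, an inhibitor of NF-kappaB signalling, fell 1.85-fold (SE 0.09), MYC 1.68-fold (SE 0.11), KLF6 1.92-fold (SE 0.16) and LMOD1, an actin nucleator gene of smooth muscle, 1.63-fold (SE 0.08), and the heme oxygenase gene HMOX1 rose 1.86-fold (SE 0.17). Adjusted over the list alone, 10 secretory, 4 matrix, 3 contractile and 9 immediate early genes fell, 4 immediate early genes and 3 NRF2 targets rose, and no other member passed. The contractile list was also lost in the design as fixed (adjusted p = 0.0788) and without untreated replicate 1 (0.0663). The median of the NRF2 targets was 0.21 without nutlin-3a replicate 1. In all 580 genes and probes passed (242 up, 338 down), 87 by at least 2-fold, against 125 in the design as fixed (114 shared), 190 with the Feature Extraction signals and 220 without background correction. It was 303 with an offset of 10 and 291 in a fit of the control channel alone. The count also depended on single arrays, at 59 and 14 without untreated replicates 1 and 2 and 232 and 1605 without nutlin-3a replicates 1 and 2.

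In BRD7 shRNA cells nutlin-3a raised BTG2 4.97-fold (log2 2.31, SE 0.13, n = 2 per state, adjusted p = 0.000700), TP53INP1 3.43-fold (SE 0.09), GDF15 3.32-fold (SE 0.22), CDKN1A 3.32-fold (log2 1.73, SE 0.11), SESN1 2.88-fold (SE 0.12) and MDM2 2.54-fold (log2 1.35, SE 0.08). INKA2 rose 3.36-fold (SE 0.09), TRIAP1, an apoptosis inhibitor gene, 2.34-fold (SE 0.11), SESN2 2.25-fold (SE 0.09) and CCNG1 1.54-fold (SE 0.07), while FAS (log2 0.45, SE 0.08) and TP53I3 (log2 0.52, SE 0.10) did not pass. Of the 67 p53 targets 21 rose, none fell and 46 did not pass (median 0.42, camera adjusted p = 1.50e-18, or adjusted p = 0.407 with an estimated correlation), and 36 rose and 3 fell adjusted over the list alone. Of the G2/M list none of the 43 genes passed (median -0.10, camera adjusted p = 0.00471, or adjusted p = 0.917 with an estimated correlation), and 1 rose and 2 fell adjusted over the list alone. Of the G1/S and replication list 1 of 46 rose (median -0.12, adjusted p = 7.73e-05, or 0.917 as an adjusted p with an estimated correlation), and 1 rose and 3 fell adjusted over the list alone. Both list calls were lost without untreated replicate 2 (medians -0.01 and -0.03, adjusted p = 0.616 and 0.292) and without nutlin-3a replicate 1 (medians -0.06 and -0.05, 0.0806 for both). The median of the G1/S list was -0.25 without untreated replicate 1 and -0.26 without nutlin-3a replicate 2. PLK1 had a log2 response of -0.34 (SE 0.10), CDT1 -0.89 (SE 0.17) and CCNE1 -0.68 (SE 0.13), and none of these passed.

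KRTAP1-5 fell 3.11-fold in BRD7 shRNA cells (log2 -1.64, SE 0.16), TM4SF1 2.95-fold (SE 0.14), RASGRP1, a Ras activator gene, 2.82-fold (SE 0.10), CXCL1 2.65-fold (SE 0.23), and the hyaluronan synthase gene HAS2 2.63-fold (SE 0.11). Secretory factors (median -0.24, camera adjusted p = 5.81e-07, 5 of 34 fell), matrix genes (-0.13, 7.73e-05, 1 of 40), contractile genes (-0.27, 7.73e-05, 2 of 22), immediate early genes (-0.17, 0.00315, 2 of 27 fell and 1 rose) and keratinocyte markers (-0.14, 0.00244, 0 of 15) passed downwards as lists. NRF2 targets passed upwards (0.13, 0.0144, 1 of 19), but not with the Feature Extraction signals (adjusted p = 0.145). The adjusted p with an estimated correlation was 0.589 for matrix genes, 0.430 for contractile genes and 0.407 for the other 4 of these lists. Without untreated replicate 1 the median was -0.12 for contractile genes and 0.20 for NRF2 targets. Without nutlin-3a replicate 2 it was -0.17 and 0.21 for these, and -0.27 for immediate early genes. PLAU, the urokinase gene, fell 1.74-fold (SE 0.13), ICAM1, an adhesion receptor gene, 1.65-fold (SE 0.08) and MYC 1.73-fold (SE 0.11), and HMOX1 rose 2.04-fold (SE 0.17). Adjusted over the list alone, 12 secretory, 1 matrix, 4 contractile and 9 immediate early genes fell, 4 immediate early genes and 2 NRF2 targets rose, and no keratinocyte marker passed. In all 258 genes and probes passed (116 up, 142 down), against 24 in the design as fixed, 21 with the Feature Extraction signals (17 up, 4 down), 86 without background correction, 112 with an offset of 10 and 6 in a fit of the BRD7 shRNA channel alone. The count was 8 and 1 without untreated replicates 1 and 2, and 41 and 565 without nutlin-3a replicates 1 and 2. Of the calls in the 2 cell types 92 were shared upwards and 116 downwards with 0 opposite, where independent lists would share 1.21 and 2.06; both responses were read on the same spots, so part of the excess may come from shared spot effects.

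The difference between the 2 responses, which is also the knockdown effect in treated minus untreated cells, addressed whether BRD7 knockdown changes the response to nutlin-3a. The fall of cell cycle genes was smaller in BRD7 shRNA cells. The G2/M list had a median log2 difference of 0.37 (camera adjusted p = 2.27e-33, or adjusted p = 0.597 with an estimated correlation), with 0.39 and 0.35 for the single hairpins. The G1/S and replication list had a median of 0.34 (adjusted p = 2.77e-24, or 0.597 as an adjusted p with an estimated correlation), with 0.36 and 0.32. The summed response of their 89 genes in BRD7 shRNA cells was 28.4% of that in control cells. Both lists passed again with median centring, at 0.50 and 0.45 above the median of all genes, which was 0.11 (adjusted p = 8.40e-19 and 9.77e-13). Among their members PLK1 had a difference of 0.60 (SE 0.10), CDCA8 0.70 (SE 0.11), UHRF1 0.71 (SE 0.14), CDT1 0.70 (SE 0.16) and CDC6, which loads the replicative helicase, 0.70 (SE 0.14). No single gene passed among all tested, while 33 G2/M and 19 G1/S genes passed upwards adjusted over the list alone.

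With the loess correction the p53 targets rose less in BRD7 shRNA cells than in control cells, and with median centring this was not seen. The median difference over the 67 genes was -0.14 (SD over genes 0.153, camera adjusted p = 1.22e-08, or adjusted p = 0.597 with an estimated correlation). Of these genes 52 had the smaller response in BRD7 shRNA cells (exact two-sided sign test across genes, p = 6.46e-06, a description since genes are not independent). The summed response was 79.0% of that in control cells, at 78.2% with hairpin 1 and 79.7% with hairpin 2. With median centring, and relative to the median of all genes, the median difference was -0.02 (hairpins -0.03 and 0.02), with 37 of 67 genes smaller (exact sign test p = 0.464) and 96.7% of the control response. In that setting the Cy3 values spread from 122% to 131% as widely as the Cy5 values on the single arrays. It therefore cannot decide whether the p53 response was smaller in BRD7 shRNA cells. CDKN1A had a difference of -0.39 (SE 0.10), TIGAR -0.43 (SE 0.10), BTG2 -0.32 (SE 0.14) and SESN1 -0.40 (SE 0.12), none of which passed alone (smallest adjusted p = 0.857), and 0 p53 targets passed adjusted over the list alone. The BTG2 log ratio went from 0.10 untreated to -0.45 treated with hairpin 1, but from 0.01 to -0.08 with hairpin 2. At the second SESN1 probe the mean log ratio was 0.19 untreated and -0.01 treated, a smaller difference. For CCNG1 it was -0.17 and -0.16, so that gene showed almost no difference. Secretory factors had a median of -0.08 (adjusted p = 0.0357, 0.597 with an estimated correlation, 0 of 34 passed adjusted over the list alone). This list was lost in the design as fixed (0.160), with no filter on dim probes (0.134), with median centring (0.0635) and without untreated replicate 1 (0.204) or nutlin-3a replicate 1 (0.0949). The genes of smallest p, none past the threshold, were HMGB2 (log2 0.77, SE 0.10), FAM72D (0.71, SE 0.10) and the cyclin A2 gene CCNA2 (0.65, SE 0.10) upwards. Downwards they were PDGFA, a growth factor gene (-0.51, SE 0.09), and CXCL2, a chemokine gene (-0.57, SE 0.13). In all, limma called 0 of 23289 here (1137 at an unadjusted p under 0.05), as did the design as fixed (1464) and the Feature Extraction signals (1411); 8 passed without untreated replicate 1, and 100 and 277 without nutlin-3a replicates 1 and 2.

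**Figure D3:**
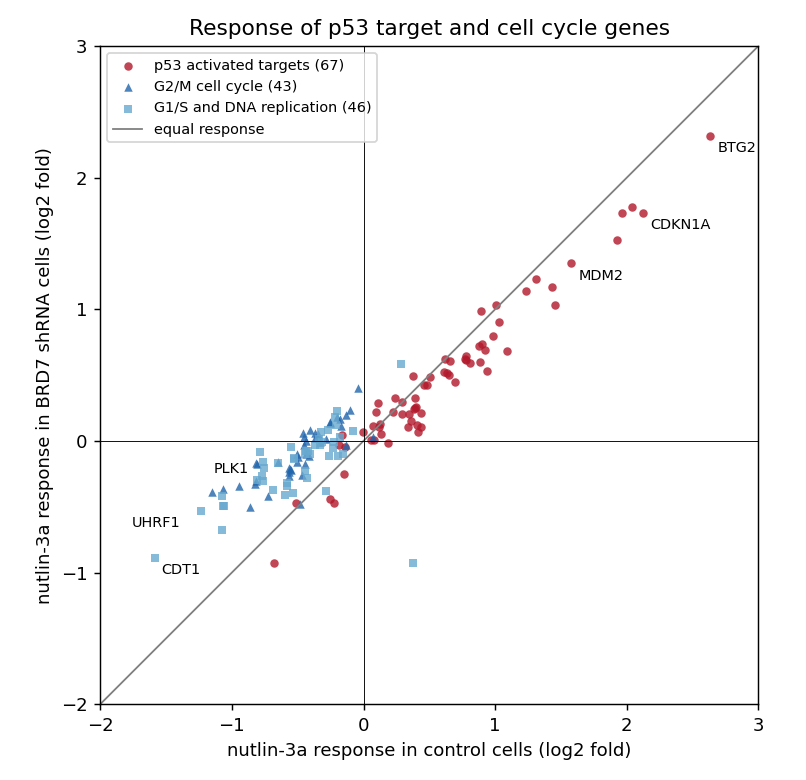
Log2 response to nutlin-3a in control cells (horizontal) and in BRD7 shRNA cells (vertical) of 67 p53 targets (circles), 43 G2/M genes (triangles) and 46 G1/S and replication genes (squares), 1 point per gene; the grey line marks equal responses. Most cell cycle genes lie left of 0 and above the line, with medians of -0.45 and -0.44 in control cells and -0.10 and -0.12 in BRD7 shRNA cells, and 52 of the 67 p53 targets lie below it, a margin that was not kept with median centring.

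The 2 hairpins were compared over both conditions, with the longer treatment on hairpin 2 per the titles. No single gene passed with limma (2446 at an unadjusted p under 0.05, smallest adjusted p 0.0754), nor in the design as fixed (1227) or with the Feature Extraction signals (1728); 96 passed with median centring, 2 with no filter on dim probes and 7 with the strict filter. The genes of smallest p were MT1F, a metallothionein gene (log2 1.26, SE 0.08, n = 2 per hairpin), and ZNF219 (1.17, SE 0.08), higher with hairpin 2, and EXOSC3, an RNA exosome subunit gene (-1.58, SE 0.08), and C3orf52 (-1.57, SE 0.08), lower with it. BRD7 itself had a difference of -0.37 (SE 0.09, adjusted p = 0.365). The G1/S and replication list was higher with hairpin 2 (median 0.22, camera adjusted p = 7.48e-12), as were the G2/M list (0.16, 2.68e-08), the interferon-stimulated genes (0.11, 0.000439) and the cholesterol genes (0.06, 0.0246). The adjusted p of these 4 lists and of the 3 that follow was 0.610 with an estimated correlation, and none of the 7 passed with fry. Lower with it were the TGF-beta response (-0.16, 0.00250), hypoxia (-0.06, 0.00240) and p53 lists (-0.03, 0.0246), all 3 of which were lost with median centring (adjusted p = 0.153, 0.267 and 0.793). The TGF-beta list was also lost in the design as fixed (0.0748), and the p53 and cholesterol lists with the Feature Extraction signals (0.0883 and 0.125). DTL, a ubiquitin ligase subunit gene of replication control, had a difference of 0.45 (SE 0.08), MX1, an interferon-induced GTPase gene, 0.60 (SE 0.10), CA9, the hypoxia-induced carbonic anhydrase gene, -0.99 (SE 0.08) and PMEPA1, a TGF-beta target gene, -0.59 (SE 0.09), and none passed. Adjusted over the list alone, 2 interferon genes and 2 TGF-beta genes were higher, 6 TGF-beta and 2 hypoxia genes were lower, and no member of the other 4 lists passed. The fit left 1 residual degree of freedom.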

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

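Of the tests weighed here, the scale of the Cy3 channel over responding genes and over the spread of values, and the position of genes called without the surface correction, were set before their results were seen. All others were chosen afterwards: both tests of second probes, swapped arrays, genes chosen on the other hairpin, median centring of the list differences, and the cell cycle genes. The lists below stood out because the knockdown effect differed between untreated and nutlin-3a-treated cells, or between hairpins, by the camera test of the difference itself. None of them passed with fry or with an estimated correlation (adjusted p = 0.597 for each list between conditions and 0.610 for each between hairpins). The test with an estimated correlation had 2 residual degrees of freedom between conditions and 1 between hairpins, so its losses do not decide whether these calls are real. In the first group the median differences were 0.37 for the G2/M list, 0.34 for the G1/S and replication list, -0.14 for the p53 targets and -0.0786 for the secretory factors. Between hairpins they were 0.22 for the G1/S list, 0.16 for the G2/M list, 0.11 for interferon-stimulated genes, 0.0612 for cholesterol genes, -0.16 for the TGF-beta response, -0.0614 for hypoxia and -0.0338 for the p53 targets. Hairpin and hours of treatment go together in treated cells per the titles, so these cannot be separated there.

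A smaller response to nutlin-3a in BRD7 shRNA cells may come from the dyes, as BRD7 shRNA RNA was always in Cy3. For the cell cycle genes a generally narrower Cy3 scale is argued against: their summed response in Cy3 was 30.6% and 39.4% of that in Cy5 on the arrays of hairpins 1 and 2, while responding genes outside the lists stood at 87.5% and 86.3% by the same measure, which takes the outside genes and every direction from the other hairpin's arrays. For the p53 targets, at 74.0% and 81.4% by this measure, a narrower scale stays open because those outside genes were below 90% too, and the intensity-dependent dye correction stays open because with median centring the median difference was -0.0206. Both tests set beforehand were void: the outside genes at 82.9% were selected partly on the control channel (79.0% for genes called in control cells and 103% for genes called in BRD7 shRNA cells), and the spread of Cy3 values at 99.9% of that of Cy5 is fixed by the loess step (122% to 131% with median centring). Outside genes that respond to nutlin-3a may also depend on p53, so a weaker response of BRD7 shRNA cells as a biological effect of the knockdown remains an untested hypothesis.

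The genes that differed between BRD7 shRNA and control cells over all arrays may partly reflect dye bias. Bias or position of single probes as the whole cause is argued against, since a second probe of the same gene had the same sign for 1777 of 2141 called genes (83.0%), against 63.6% of 2584 genes that were not called. Dye bias of a whole transcript cannot be told apart from the knockdown, because the number of arrays with swapped dyes is 0. An effect of the BRD7 knockdown stays open beside it.

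Over all arrays 4847 genes were called only without the surface correction. Of these, 4835 (99.8%) had the sign of the trend fitted at their probe, against 84.2% of the 4795 genes called with and without it. This share decides nothing, because the genes were selected by losing their call when the trend was removed. A second probe elsewhere on the array, with the trend removed, had the same sign for 705 of 1235 of these genes (57.1%). Among genes not called with the correction, whose own sign was taken with the trend removed, it was 63.6%. The same selection lowers the share of 57.1% by itself, so that share does not decide the question either. Position may account for many of these calls, and real effects of small size stay open. No biological explanation was tested for them.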

How the results depend on the processing

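The surface correction with its spans, and median centring of lists, of the p53 response and relative to all genes were added after the data were seen. All other settings were set before, and the fit without the surface correction is the design as fixed. Counts of genes called in both settings stand in brackets, and the cause of a change was not tested unless named. In the design as fixed, without the surface correction, 6405 [1826] genes passed in untreated cells, 125 [114] in the response of control cells and 24 [24] in that of BRD7 shRNA cells, while MDM4 (-0.36), TP53INP1 (-0.17), BTG2 (0.14) and CCNG1 (0.21) turned over all arrays, as did BRD7 (-0.39) and CNN1 (0.00996) in control cells. A span of 0.05 turned only TP53I3 (-0.00399), and 0.3 no named gene. With the Feature Extraction signals the counts were 0 (6735 at an unadjusted p under 0.05) untreated, 1887 [1282] with nutlin-3a, 190 [116] in control and 21 [17] in BRD7 shRNA cells, 2 lists passed in untreated cells, BRD7 was at -5.83, and MDM4 (-0.0329) and TP53I3 (-0.0225) turned. The deposited ratios gave 0 untreated and 1907 [1301] with nutlin-3a, and turned MDM4 (-0.0304) and TP53I3 (-0.0238). Without background correction the counts were 4 [4], 0 (7468 at an unadjusted p under 0.05), 5080 [4593] over all arrays, 220 [206] and 86 [85], BRD7 was at -5.26 and TP53I3 at -0.0167. With an offset of 10 they were 12 [12], 2717 [2591], 303 [281] and 112 [109], BRD7 was at -5.43 and TP53I3 at -0.0187. Median centring, which leaves the intensity-dependent dye difference in the ratios and moved the median of all tested genes by 0.55 untreated, 0.68 with nutlin-3a and 0.62 over all arrays, gave 20396 [2025], 20876 [3193], 21502 [5091] and, between hairpins, 96. Under it 14 lists passed in each of these 3 knockdown comparisons and 8 in their difference, and the p53 difference was -0.0206. Relative to all genes PLXNB2 (0.0519) and ALDOA (0.0578) then turned with nutlin-3a, OR11A1 (0.0359) in the difference, and MDM2 (-0.47), MDM4 (-0.0103), BTG2 (0.36), CCNG1 (0.36), PLK3 (0.22) and ALDOA (0.13) over all arrays. Between hairpins no filter gave 2 and the strict filter 7. Fits of 1 channel gave 291 [228] and 6 [6] for the responses of control and BRD7 shRNA cells, and only the 2 untreated arrays gave 5527. The mean over probes turned MDM4 (-0.0802) and no normalization between arrays CNN1 (0.0215), both in control cells. With an estimated correlation 0 lists passed in any of the 7 comparisons, and with fry 0 passed in 5 of them, with 3 over all arrays and 6 in control cells. The test with an estimated correlation has only the residual degrees of freedom of each fit (2, or 1 for the hairpins).

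The hairpin numbers make 2 pairs, and no label says that a number marks a shared culture or day; the deviations of arrays with the same number correlated at 0.276. For the 2 responses the number was used as a replicate block in fits of 1 channel. These gave 39 [37] calls in control cells and 162 [115] in BRD7 shRNA cells, against 291 and 6 in fits of 1 channel without the block. In the other comparisons the block kept the counts within 1.5 times (4322, 6454, 0 with 1834 at an unadjusted p under 0.05, and 9613). Leaving out 1 array at a time, with the lone array of a condition assumed to vary like the others, gave from 28 to 5527 calls untreated, 3522 to 4162 with nutlin-3a, 0 to 277 in the difference, 3902 to 8386 over all arrays, 14 to 1605 in control cells and 1 to 565 in BRD7 shRNA cells; the lowest came without untreated replicate 2, except that both untreated arrays gave 3522, and 277, 8386, 1605 and 565 came without nutlin-3a replicate 2. The hairpin comparison leaves no residual degree of freedom then and was not run. Named genes that turned in some of these fits were TP53I3 (from -0.0162 to 0.0208) over all arrays and MDM4 in control cells (-0.138 to 0.183). In BRD7 shRNA cells they were BRD7 (-0.108 to 0.276) and MDM4 (-0.0578 to 0.119); none of these values was called as reported. Of 297 named values, 233 kept direction and side of the threshold in the design as fixed, 203 with the Feature Extraction signals, 204 without background correction and 246 with an offset of 10. The dim control channel, with a median signal between 57 and 71.5 over a background of 35, limits the precision of genes of low level.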

Other observations

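Apart from the lists described with each comparison, several gene groups did not pass the camera test of the knockdown over all arrays. With median centring 14 of the 21 lists passed it. SWI/SNF subunits, the complexes of which BRD7 is a part, did not pass (median 0.07, camera adjusted p = 0.770), with 9 of 26 genes higher and 3 lower; the mean, which includes BRD7 itself, was -0.10. The unfolded protein and amino acid stress genes (median -0.10, adjusted p = 0.160) had 7 of 33 higher and 12 lower, the heat shock genes (-0.03, 0.427) 4 of 17 higher and 4 lower, and the oxidative phosphorylation genes (0.06, 0.308) 9 of 41 higher and 2 lower. The oxidative phosphorylation list passed upwards with fry (adjusted p = 0.0415), with 28 of 41 log2 ratios above 0. Interferon-stimulated genes (0.03, 0.947) had 15 of 42 higher and 8 lower, immediate early genes (0.14, 0.176) 11 of 27 higher and 3 lower, secretory factors (-0.06, 0.203) 8 of 34 higher and 10 lower, and matrix genes (-0.02, 0.183) 5 of 40 higher and 11 lower. Contractile genes (0.02, 0.806), cholesterol genes (0.04, 0.708), NRF2 targets (-0.02, 0.947) and the TGF-beta response (0.01, 0.688) did not pass either.

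Markers of other cell types that skin can hold did not pass over all arrays. The medians were -0.04 for keratinocyte (15 genes, adjusted p = 0.308), -0.16 for melanocyte (3 genes, 0.176), 0.01 for endothelial (7 genes, 0.947) and -0.09 for leukocyte markers (12 genes, 0.0987).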
